A study of Rattus norvegicus with 192 samples.

How the data were processed

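The series measured polyA RNA by sequencing in the nucleus accumbens core of outbred heterogeneous stock rats, as part of a cohort in which other brain regions were also sampled. The labels list 192 libraries, and the deposited table used here holds 159 of them. The remaining 33 carry a note of removal in the labels, 32 because no genotype matched and 1 without a stated reason, and were not analysed here. The labels give no treatment, sex, age, date or sequencing batch. Libraries were therefore grouped by the label itself. There were 67 libraries with an all-digit rat identifier (numeric label), 77 with an identifier starting with E21 (E21 label) and 2 with an identifier starting with AA1. A further 13 libraries had a label that the submitters had corrected from the genotype, 12 of them to the E21 format (corrected E21 label) and 1 to another format. Each of these 13 had carried a label of one numbered series of libraries with no known rat before the correction, and the 32 libraries with no matching genotype belong to the same series. The label groups can therefore stand for batches of dissection or library preparation that no label names. Each library carries a different rat identifier and was taken as 1 rat. The highest correlation between any pair of libraries was 0.994, and none were merged.

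Reads were quantified with kallisto 0.48, per the submitters' processing notes, and the annotation, the genome build and the way transcripts were summed to genes are not given in the sources used here. The deposited values are log2 of an expected count plus 1 for each of 38354 genes, not scaled to library size. This was read from the values, since the file header names neither a unit nor a build. Of the gene symbols, 38278 occurred in the RefSeq gene table of the rat assembly GRCr8, which was used for names and for the order of neighbouring genes. No mitochondrial genes were in the table, so a preset list of mitochondrial transcripts and its pairing with ribosomal protein genes were not analysed here. Values were turned back to expected counts, scaled to a total of 1000000 per library (CPM) and log2 transformed with a pseudocount of 1. Fold changes are on this scale and understate the change of low genes. Because counts are estimates from pseudoalignment, the values of genes with near-identical copies, pseudogenes or overlapping neighbours are uncertain, since reads can be shared between them. Library strand is not given in the sources used here, so antisense and overlapping genes could not be told apart from their partners. Total expected counts had a mean of 24.8 M per library (SD 7.17, n = 159, M standing for 1000000) and ranged from 14.6 to 61.2 M. A level of 1 CPM was thus 14.6 expected counts in the shallowest library and 61.2 in the deepest. Genes with a mean of at least 1 CPM were tested, which left 15427 genes.

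Groups were compared with limma 3.58.1 in R 4.3.3, by its moderated test, on both sides, with an intensity trend and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p of 0.05. Counts were also made at an absolute log2 change of at least 0.5. Of 33 gene lists fixed in advance, 31 had at least 2 tested genes and were tested with limma's camera at its preset correlation, and again with a correlation estimated for each list. The lists without tested genes were the blood leukocyte list and the mitochondrial one. The list score of a library was the mean over members of their standardised log2 values. Between-rat SD was taken over log2 values, and the SD and mean pairwise r of each list were set against 10000 and 1000 random lists matched on expression. Correlations between list scores had permutation p-values, on both sides, from 100000 resamples, whose smallest value is 1e-05, adjusted over the family of 15 pairs. A gene was said to have 2 separated levels if its sorted log2 values held a gap of at least 1 with at least 5% of libraries on each side, and 20 sets of normal draws gave the number reached by chance. Correlations of neighbouring genes were compared with 1000 shuffles of positions, whose smallest p is 0.001. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

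Groups, tests, gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where stated. By that rule the text names the 10 genes with the largest rise and the 10 with the largest fall per comparison among genes passing limma's threshold, up to 4 members of each list with the smallest p, the 15 genes with the highest and the 5 with the lowest SD at a mean of at least 10 CPM, the 10 genes with the highest mean and the 10 with the widest gap. Symbols made from a locus number were left out, and some genes that the rule takes are not reported here. Other genes were chosen after their values were seen, and the marker genes used to describe library profiles are among them. After the data were examined, 11 libraries were set apart by the widest gap on the first principal component and 1 by the widest gap in the ratio of Slc17a7 to Drd1 (12 libraries). They stayed in the limma, SD and separated-level results, which were repeated without them. Correlations, coherence and neighbouring genes were computed over the remaining 147 libraries, in departure from the plan for all 159, because no pooled correlation is meaningful over separate clusters. Planned differences between the levels of different genes within a rat were not run, because expected counts are not scaled by transcript length and no transcript lengths were at hand. A planned comparison of removed with retained libraries was not run, since the removed ones had no values.

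The procedures were tested on simulated data made from these libraries. With 100 genes changed by 0.5 and 100 by 1 on the log2 scale among 15427, limma recovered 91% and 99% of them in the comparison of formats, and 6.4% of its calls were false. At the sizes of the comparison after label correction it recovered 74% and 96%, and 2.86% of its calls were false. In these simulations each gene varied independently, with no clusters or batches of libraries. The shares of false calls therefore need not hold in the real libraries, where random splits called up to 2162 genes between formats and 1817 after label correction. The search for separated levels found 99.5% of 200 genes given levels 3 apart. Alternatives covered the filter, the pseudocount, median-of-ratios and quantile scaling, covariates, the omission of 27 libraries whose median correlation with the others was low, the Wilcoxon rank-sum test and voom. Their effect is given in the closing section.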

Results

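RNA of the nucleus accumbens core, a ventral striatal region built mostly of medium spiny neurons, was profiled in 159 outbred rats. Total expected counts were 28.0 ± 8.56 M (SD, n = 67) in libraries with a numeric label, 22.3 ± 4.92 M (SD, n = 77) with an E21 label and 24.1 ± 3.86 M (SD, n = 12) with a corrected E21 label. The remaining 3 libraries had between 18.1 and 19.8 M. Among genes whose symbol is not made from a locus number, the myelin gene Mbp had the highest mean level, at 8486 CPM. Zfp532, Scd2, Slc1a2, Eef1a1, Apoe, Zwint and Mobp were also among the 10 highest of these, down to 2435 CPM for Mobp. Some locus-number genes annotated as ribosomal RNA were higher than Mobp, such as LOC120093067 at 4000 CPM. These levels are not scaled by transcript length. Zfp532 had a median of 2028 CPM over 147 libraries and reached 91845 in one of them.

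Most libraries had the profile of medium spiny neurons, with Drd1 (the D1 dopamine receptor) between 154 and 441 CPM, Ppp1r1b between 998 and 2989 and Penk (the enkephalin precursor) between 509 and 1912 in 147 libraries. In 11 libraries Drd1 lay between 1.61 and 7.77 CPM and Adora2a (an adenosine receptor) between 3.45 and 11.1. The same 11 had Th (tyrosine hydroxylase, the first enzyme of dopamine synthesis) between 630 and 2107 CPM, where the 147 others had 0.222 to 10.7. Slc6a3, the dopamine transporter, lay between 236 and 1088 CPM in them and at 2.98 or less in the others. En1, a midbrain transcription factor, lay between 77.7 and 202 and at 0.829 or less. Of these 11 libraries, 10 had a numeric label (numbers 4, 34, 53 to 58, 62 and 63) and 1 an E21 label (number 70). A further library of the numeric label (number 3) had 1993 CPM of Slc17a7, the vesicular glutamate transporter of cortical neurons, 174 of Tbr1 and 20.0 of Drd1. On the first principal component, which held 35.7% of the variance, the 11 libraries lay at -90.4 or below and the others at -23.0 or above.

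**Figure D1:**
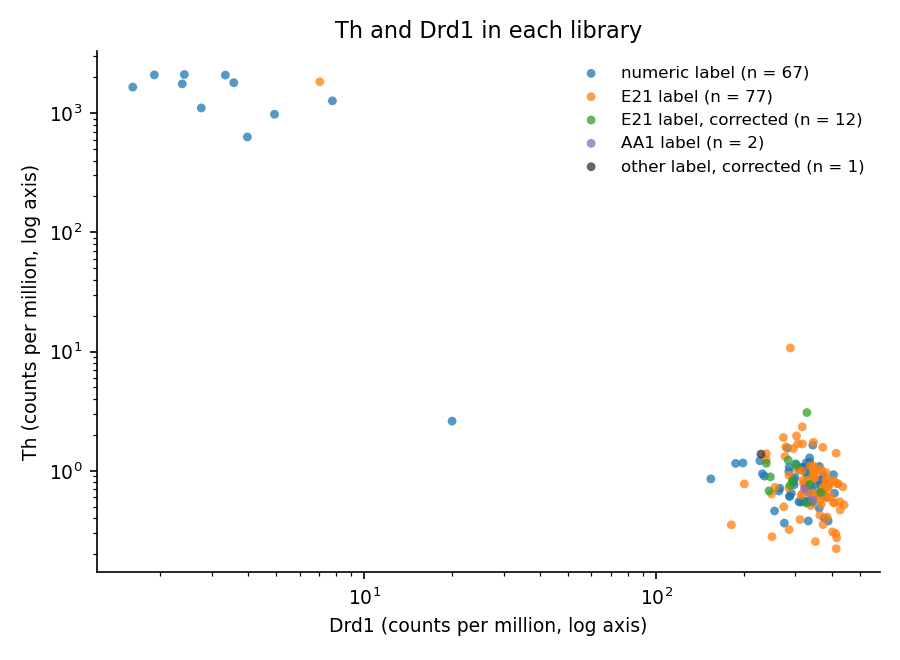
Each point is 1 library, with Drd1 on the x axis and Th on the y axis in CPM on log axes, coloured by label group. In 11 libraries Th was at 630 or more with Drd1 at 7.77 or less, and the numeric library with Drd1 at 20.0 had Th at 2.61.

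The format of the rat identifier is the one label that divides the original libraries, and the comparison of formats asks whether expression differed along it. Genes of medium spiny neurons were higher in the 77 E21 libraries than in the 67 numeric ones. On the log2 scale Drd1 rose from 7.29 ± 2.28 (SD, n = 67) to 8.34 ± 0.67 (SD, n = 77), with mean levels of 263 and 340 CPM, and the mean level of Adora2a rose from 263 to 352 CPM. Ankrd63, Cartpt, Arpp21 and Six3 were also among the 10 largest rises. Among the 10 largest falls were those of Slc17a6 (a vesicular glutamate transporter), Th, Kcnj6, Slc6a3, Cck (cholecystokinin), Nr4a2, Chrna4 and Cadps2. The largest fall was that of the pseudogene Rps14-ps7, from 92.2 ± 35.3 to 38.9 ± 37.1 CPM. The 3 largest rises were those of Rn45s, annotated as a ribosomal RNA precursor, Cox7a2l2 and Rpl37. Levels of Cox7a2l2, Rplp2l2, Rps14-ps7 and other gene copies are uncertain, since near-identical genes can share reads.

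In limma, log2 changes were 1.05 for Drd1 (SE 0.27, adjusted p = 0.000739), 1.05 for Adora2a (SE 0.25, adjusted p = 0.000284) and -1.31 for Th (SE 0.42, adjusted p = 0.00663). Without the 12 libraries of midbrain or cortical profile, in an alternative chosen after the data were examined, the change of Drd1 was 0.13 (SE 0.046, limma adjusted p = 0.0163) and that of Adora2a 0.19 (SE 0.042, limma adjusted p = 0.000135). With the cortical score as a covariate as well, both changes shrank and both calls ended, at 0.025 for Drd1 (SE 0.043, limma adjusted p = 0.666) and 0.053 for Adora2a (SE 0.032, limma adjusted p = 0.178). So did those of Ankrd63, from 0.11 (SE 0.043) to -0.018 (SE 0.037, limma adjusted p = 0.725), and Arpp21, from 0.16 (SE 0.036) to 0.041 (SE 0.028, limma adjusted p = 0.233), while Cartpt at 0.26 and Six3 at 0.14 passed. The call of Th ended without the 12 alone, at 0.019 (SE 0.064, limma adjusted p = 0.842), and so did that of Slc6a3, at -0.0027 (SE 0.039, limma adjusted p = 0.962). Rn45s (1.39, SE 0.18), Cox7a2l2 (1.22, SE 0.16), Rpl37 (1.12, SE 0.17) and Rps14-ps7 (-2.45, SE 0.32) passed limma's threshold without them too, as did Slc17a6 at -0.93 (SE 0.14). With the cortical score as well, Slc17a6 shrank to -0.35 (SE 0.079), Kcnj6 to -0.25, Chrna4 to -0.16 and Cadps2 to -0.17, which passed. The calls of Nr4a2, which went from -0.91 (SE 0.20) to -0.041 (SE 0.086, limma adjusted p = 0.724), and Cck, from -0.88 (SE 0.24) to 0.17 (SE 0.086, limma adjusted p = 0.0909), ended. Cortical genes took the leading places among the falls without those 12, led after 2 gene copies by Slc17a7 at -1.39 (SE 0.31, limma adjusted p = 0.000203), Ccn3 at -1.15 and Tbr1 at -1.14 (SE 0.25, limma adjusted p = 0.000114). With all libraries the change of Slc17a7 was -0.74 (SE 0.36), which did not pass limma's threshold (adjusted p = 0.0807). Limma called 7355 of 15427 genes, 2688 higher and 4667 lower in E21 libraries, a share of 36.5% higher. With median-of-ratios scaling the share was 50.3% and with quantile normalization 53.5%, so the balance of directions depended on the scaling. At an absolute log2 change of at least 0.5, limma called 488 genes, 138 higher and 350 lower. Without the 12 libraries the counts were 5796 and 178.

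Among the preset lists, all 12 shared medium spiny neuron genes rose, with Ppp1r1b at 0.84, Rarb at 0.70, Arpp21 at 1.02 and Gng7 at 0.87 on the log2 scale, and 12 rose adjusted over the list alone. Limma's camera called the list higher (adjusted p = 4.36e-05; adjusted p = 0.68 with an estimated correlation). All 6 genes of the D2 medium spiny neuron list rose, 6 adjusted over the list alone, with Gpr6 at 0.94, Gpr52 at 0.62 and Drd2 at 0.34 (camera in limma, adjusted p = 0.00118; adjusted p = 0.68 with an estimated correlation). Of the D1 list, 5 genes rose and Sfxn1 fell, with the same counts adjusted over the list alone, and Pdyn (prodynorphin) changed by 0.80 and Tac1 by 0.58 (limma's camera, adjusted p = 0.0277; adjusted p = 0.68 with an estimated correlation). Immediate early genes, which neurons induce on activity, rose in 9 of 16 cases and fell in 2, with the same counts adjusted over the list alone. Nr4a1 changed by 0.64, Junb by 0.50, Dusp1 by 0.28 and Fosb by 0.55 (limma's camera, adjusted p = 0.00983; adjusted p = 0.68 with an estimated correlation). Clock output genes rose in 4 of 9 cases, and in 5 adjusted over the list alone, with Bhlhe41 at 0.22 and Nr1d1 at 0.18 (limma's camera, adjusted p = 0.0206; adjusted p = 0.68 with an estimated correlation). The Bmal1 arm rose in 4 of 5 genes, 4 adjusted over the list alone, with Cry1 at 0.17, Bmal1 at 0.19 and Npas2 at 0.45 (limma's camera, adjusted p = 0.0359; adjusted p = 0.68 with an estimated correlation). All 7 meningeal fibroblast genes fell, 7 adjusted over the list alone, with Col3a1 at -0.70, Lum at -0.59, Col1a2 at -0.75 and Igf2 at -0.84 (limma's camera, adjusted p = 0.0127; adjusted p = 0.68 with an estimated correlation). Mural genes fell in 5 of 6 cases, 5 adjusted over the list alone, with Myh11, a smooth muscle myosin, at -0.95 and Rgs5 at -0.45 (limma's camera, adjusted p = 0.0277; adjusted p = 0.68 with an estimated correlation).

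These list calls moved with the libraries of other profile. Without the 12, the D2 list was still called higher, with 5 of 6 genes rising (limma's camera, adjusted p = 0.0011; adjusted p = 0.631 with an estimated correlation), and the shared list with 5 of 12 (adjusted p = 0.0397; adjusted p = 0.869 with an estimated correlation). The D1, immediate early, clock, meningeal and mural lists were no longer called, at limma adjusted p-values between 0.14 and 0.356. The cortical glutamatergic list was called lower instead, with 7 of 8 genes falling and 7 adjusted over the list alone (limma's camera, adjusted p = 0.0032; adjusted p = 0.869 with an estimated correlation). In it Cux2 changed by -0.34, Neurod6 by -0.93 and Neurod2 by -1.09. With all libraries 5 of its 8 genes fell, 7 adjusted over the list alone, and camera in limma did not call it (adjusted p = 0.0826). All 6 midbrain dopamine genes fell with all libraries, 6 adjusted over the list alone, though the list was not called (limma's camera, adjusted p = 0.104). The other 21 lists were not called with all libraries, at limma adjusted p-values of 0.0826 or more. With quantile normalization the calls of the D1 list (limma adjusted p = 0.0773), clock output (0.0549) and Bmal1 arm (0.0571) ended, and the cortical list was called lower (0.0388). For the oligodendrocyte and GABA interneuron lists, which were not called, the direction of the test differed in sign from the median change.

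The 12 libraries with a corrected E21 label were compared with the 77 with an original E21 label, to ask whether rats named from their genotype differed in expression. Genes of cortical projection neurons were higher in the corrected libraries. Slc17a7 rose from 174 ± 196 CPM (SD, n = 77) to 463 ± 238 (SD, n = 12), and Tbr1, a transcription factor of deep cortical layers, from 18.2 ± 18.2 to 44.7 ± 21.8. Prss12, Ccn3, Neurod2, Nxph3, Smim43 and Cplx3 were further leading rises beside the pseudogene Rps14-ps7. The leading falls were smaller, with Rn45s from 99.9 ± 115 to 29.0 ± 10.7 CPM, Calcr (the calcitonin receptor) from 33.5 ± 15.8 to 20.8 ± 9.90, and Marcks and Tmem47 with log2 changes of -0.44 and -0.40. Rpl37, Rn7sl1, Ybx1l1, Actg1l1, Rps12l2 and Rpl10l1 made up the rest, and their levels and that of Rps14-ps7 are uncertain because near-identical copies can share reads, which was not tested for these genes.

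In limma, log2 changes were 2.04 for Slc17a7 (SE 0.60, adjusted p = 0.0279), 1.66 for Tbr1 (SE 0.47, adjusted p = 0.0195), 1.70 for Prss12 (SE 0.34, adjusted p = 0.0011) and -0.40 for Tmem47 (SE 0.087, adjusted p = 0.00177). Limma called 791 genes, 659 higher and 132 lower, a share of 83.3% higher. The share was 62.7% with median-of-ratios scaling and 59.8% with quantile normalization. At an absolute log2 change of at least 0.5, limma called 214 genes, 204 higher and 10 lower. The count was 1265 without the library of midbrain profile (E21 label number 70), with all 791 genes called in the same direction. Against the 67 numeric libraries in place of the E21 ones, limma called 0 genes, with 1268 at an unadjusted p under 0.05, and no other tool was run on that reference. With the cortical, oligodendrocyte and astrocyte list scores as covariates, limma called 1 gene, Fbln7 (a fibulin, named after its value was seen) at 0.48, with 2095 at an unadjusted p under 0.05. Every corrected library came from one earlier numbered series, so that label correction and a batch cannot be told apart.

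Of the cortical glutamatergic list, 6 of 8 genes rose, 7 adjusted over the list alone, among them Emx1 at 1.11, Neurod2 at 1.61 and Neurod6 at 1.53 on the log2 scale. Limma's camera called the list higher (adjusted p = 6.39e-06; adjusted p = 0.88 with an estimated correlation). The cytosolic ribosomal protein list was called lower with a median change of -0.074, though 2 of its 81 genes fell, Rpl37 and Rpl10l1, and 0 adjusted over the list alone (limma's camera, adjusted p = 3.45e-05; adjusted p = 0.88 with an estimated correlation). Microglial genes were called lower as a list with a median of -0.083, while 0 of 11 passed the test singly, over all genes or adjusted over the list alone, with P2ry12 at -0.25 and C1qb at -0.25 (limma's camera, adjusted p = 0.0474; adjusted p = 0.88 with an estimated correlation). With quantile normalization the microglial call ended (limma's camera, adjusted p = 0.157). Without the library of midbrain profile, the D2 list was also called lower (limma's camera, adjusted p = 0.000273; adjusted p = 0.68 with an estimated correlation), with Drd2 at -0.20 and Gpr6 at -0.29 among 3 of 6 genes that fell, 5 adjusted over the list alone. So were the shared medium spiny neuron list (4 of 12 genes fell, 5 adjusted over the list alone, adjusted p = 0.000273; adjusted p = 0.704 with an estimated correlation) and the cholinergic interneuron list (adjusted p = 0.0451; adjusted p = 0.935 with an estimated correlation), in which 1 of 7 genes, Lhx8, fell by 0.37, 1 adjusted over the list alone. The other 28 lists were not called with all libraries, at limma adjusted p-values of 0.0658 or more. Among them the median, mean and test differed in sign for the red blood cell, heat shock, diencephalic, glucocorticoid, interferon and oligodendrocyte precursor lists.

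**Figure D2:**
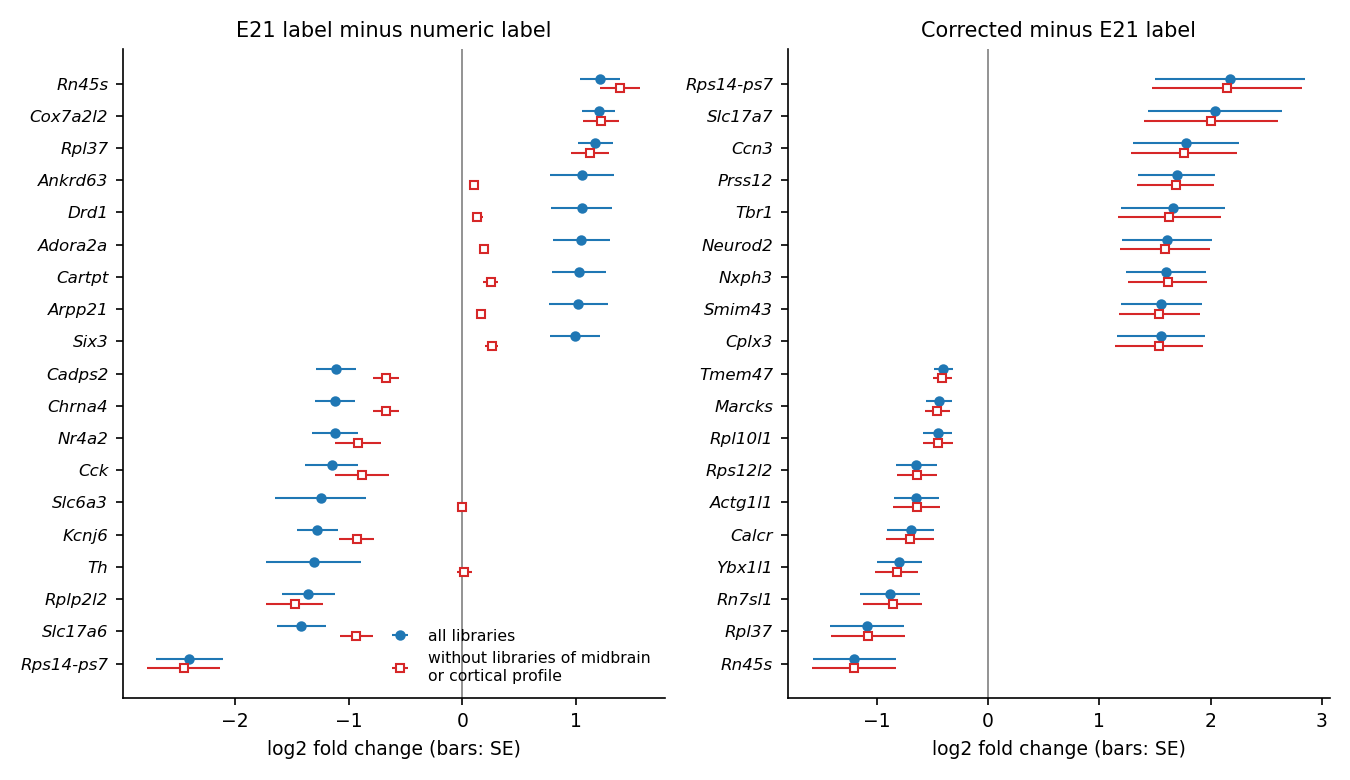
Log2 changes of the named genes of each comparison (points, bars: SE), as E21 minus numeric label on the left and corrected minus E21 label on the right, with all libraries and without the 12 of midbrain or cortical profile. Without those 12 the change of Th went from -1.31 to 0.019 between formats. After correction only 1 of the 12, E21 label number 70, was in the comparison, and without it the change of Slc17a7 went from 2.04 to 2.01.

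**Figure D3:**
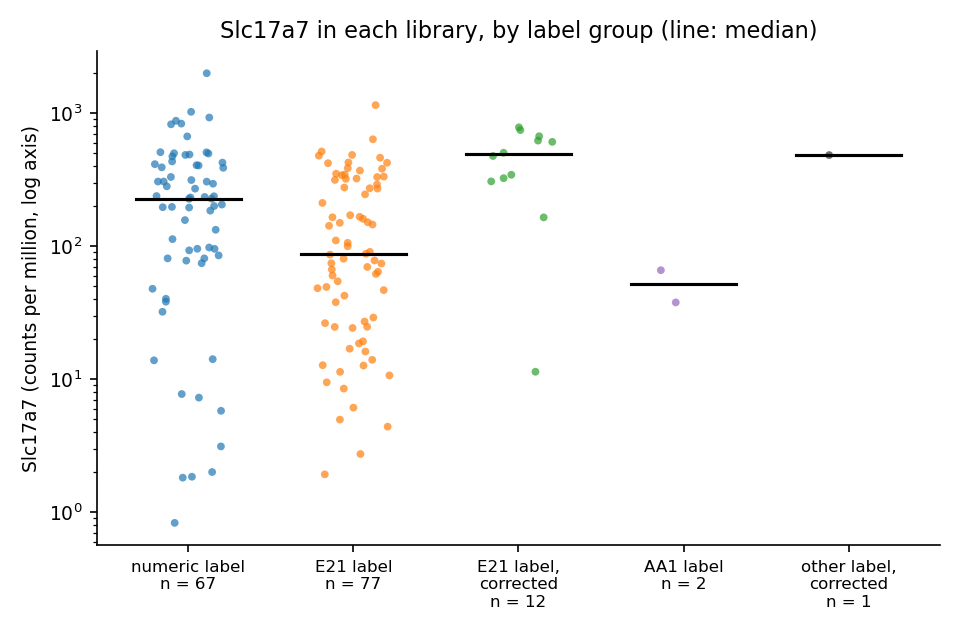
Each point is 1 library, with Slc17a7 in CPM on a log y axis, placed by label group, and the line is the group median. Corrected E21 libraries reached 781 CPM, E21 libraries 1148 and numeric libraries 1993.

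Genes varied between libraries, each of 1 rat, by a median SD of 0.27 on the log2 scale over 159 libraries, and 1791 of 15427 genes had an SD of at least 0.5. With 1 library per rat, differences between rats cannot be told apart here from those of dissection, preparation or depth. Xist, the RNA of X inactivation, had the highest SD at 4.64, followed by the Y-linked genes Ddx3y at 2.91 and Eif2s3y at 2.78. Th at 2.49, Slc6a3 at 2.37, Chrnb3 at 1.87, En1 at 1.80 and Ret at 1.73 also stood among the 15 highest. Without the 12 libraries of other profile the SD of Th was 0.36 and that of Slc6a3 0.23, and 781 genes had an SD of at least 0.5. The cortical genes Slc17a7 and Tbr1 kept SDs of 1.92 and 1.53 there, from 2.20 and 1.75 over all libraries. Beta globin genes also varied widely, with Hbbl1 at 2.22 and Hbb-b2 at 2.21, as did Kdm5d at 2.37, Rpl30l2 at 2.35 and Rps14-ps7 at 2.12. The lowest SDs were those of Eif3b at 0.068, Stau1 at 0.073, Eif4e2 at 0.075, Ube2h at 0.079 and Nono at 0.080, genes of translation, RNA binding and ubiquitin transfer. Among 147 libraries the cortical list had a median SD of 1.33, above 100% of random lists of the same size, and the red blood cell list 0.69. Housekeeping genes had 0.18, above 25.1% of random lists. Levels of the globin and ribosomal copies are uncertain because near-identical genes can share reads.

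Over all 159 libraries, 357 genes had 2 separated levels, against a mean of 0.15 in normal draws. In 84 of them the 11 libraries of midbrain profile alone formed the upper side and in 187 the lower side. Slc6a3 had the widest gap at 5.90 on the log2 scale, followed by Xist at 5.79, Th at 5.75, En1 at 5.43, Ret at 5.26, Chrna6, En2, Ddx3y, Cnpy1 and Eif2s3y at 4.36. Without the 12 libraries of other profile 16 genes were separated, and 14 of these were among the 357, with Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Hbb-b2, Rpl30l2, Ndufa10l1, Prmt1l1 and Fam111a among the 14. The other 2 were Klhl34 and Eef1a1l1. Hbb-b2 lay at 0.0047 CPM or less in 71 of the 147 libraries and at 3.30 or more in 76. Fam111a lay at 1.71 or less in 86 libraries and at 4.74 or more in 61. Xist was at 106 CPM or more in 83 of 159 libraries and at 0.932 or less in 76. On its high side were 46 of 77 E21, 31 of 67 numeric and 5 of 12 corrected E21 libraries. Among the 76 libraries with low Xist, all 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were on their high side. Only 1 library, E21 label number 20, had both, with Xist at 309 and Ddx3y at 33.1 CPM. The labels give no sex.

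Members of most preset lists varied together over the 147 libraries, measured as the mean pairwise r, and 23 of 31 lists lay above 95% of random lists of the same size and expression. Glial and vascular groups had an r of 0.72 for oligodendrocyte, 0.71 for meningeal fibroblast, 0.53 for microglia, 0.48 for ependymal, 0.46 for astrocyte, 0.45 for oligodendrocyte precursor, 0.45 for endothelial and 0.39 for mural genes. Neuronal lists had 0.75 (cortical glutamatergic), 0.62 (D2), 0.60 (cholinergic), 0.53 (shared medium spiny), 0.45 (lateral septum), 0.31 (D1) and 0.30 (neuroblast and dividing cell). Red blood cell genes had 0.72, cytosolic ribosomal protein genes 0.68, interferon response genes 0.47, immediate early genes 0.45, MHC genes 0.37, glucocorticoid response genes 0.31, clock output genes 0.30 and housekeeping genes 0.22. The lists that did not pass the 95% mark were Bmal1 arm (0.21), Y-linked and X-inactivation (0.20), GABA interneuron (0.16), diencephalic or other glutamatergic (0.12), opioid (0.097), midbrain dopamine (0.075), heat shock (0.054) and choroid plexus (-0.19), the last with 2 tested genes. The Y-linked and X-inactivation list joins genes that move in opposite directions, since Xist was low where the Y-linked genes were high. Its mean r therefore does not measure how tightly its members are coupled, and Kdm5d and Eif2s3y had an r of 0.9976. Within formats, 26 lists passed in numeric and 22 in E21 libraries. Genes are not independent replicates, and these percentiles describe the present libraries.

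Scores of medium spiny neuron lists moved together over 147 libraries and against the cortical score. D1 and D2 scores had an r of 0.77 (permutation p = 1e-05, the smallest possible, adjusted p = 1.67e-05) and a rho of 0.63 (permutation p = 1e-05, adjusted p = 1.67e-05). Without the 2 libraries farthest from the median the r was 0.71, and it was 0.78 within numeric and 0.70 within E21 libraries. D1 and shared scores had an r of 0.78, a rho of 0.71 and 0.75 without those farthest, with 0.80 within numeric and 0.74 within E21 libraries and the same p-values. The shared score fell as the cortical score rose, with an r of -0.66 and a rho of -0.67 (permutation p = 1e-05, adjusted p = 1.67e-05 for both), -0.63 without the 2 farthest, -0.71 within numeric and -0.61 within E21 libraries. Other negative relations of the shared score were weaker, with r and rho of -0.44 and -0.45 for lateral septum (adjusted permutation p = 1.67e-05 for both), -0.36 and -0.43 for astrocyte (3e-05 and 2.73e-05) and -0.33 and -0.34 for oligodendrocyte genes (5e-05 and 2.73e-05). Without the 2 farthest libraries their r was -0.39, -0.37 and -0.36. With the first principal component removed the astrocyte pair weakened to an r of -0.23 and a rho of -0.28 (adjusted permutation p = 0.00751 and 0.0011). Within numeric libraries these r values were -0.50, -0.34 and -0.36, and within E21 libraries -0.34, -0.46 and -0.35. For oligodendrocyte genes within numeric libraries the rho did not pass (-0.24, adjusted permutation p = 0.102).

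Immune, vascular and stress scores also moved together. Interferon response and MHC scores had an r of 0.61 and a rho of 0.62, microglia and interferon scores 0.45 and 0.46, cortical and GABA interneuron scores 0.50 and 0.52, red blood cell and endothelial scores 0.43 and 0.37, and immediate early and heat shock scores 0.39 and 0.44, each with a permutation p of 1e-05 and an adjusted p of 1.67e-05 over the family of 15 pairs. Without the 2 farthest libraries their r was 0.60, 0.42, 0.48, 0.41 and 0.39. Within numeric libraries these pairs had an r of 0.67, 0.47, 0.23, 0.54 and 0.39, and within E21 libraries 0.63, 0.51, 0.51, 0.36 and 0.38. The cortical and GABA pair did not pass within numeric libraries (permutation p = 0.0929, adjusted p = 0.116). Immediate early and glucocorticoid response scores moved apart, with an r of -0.32 (permutation p = 4e-05, adjusted p = 5e-05), a rho of -0.31 (adjusted permutation p = 0.000125), -0.32 without the 2 farthest, -0.33 within numeric and -0.30 within E21 libraries. Choroid plexus and ependymal scores had an r of 0.28 (permutation p = 0.00085, adjusted p = 0.000981), a rho of 0.21 (adjusted permutation p = 0.0121), 0.23 without the 2 farthest, 0.36 within E21 libraries and 0.21 within numeric ones, where they did not pass (adjusted permutation p = 0.137). The choroid plexus score rests on 2 tested genes with an r of -0.19 between them, the other 6 members being under 1 CPM, and does not stand for that tissue as a whole. Neuroblast and ependymal scores did not pass, with an r of 0.16 (permutation p = 0.0507, adjusted p = 0.0543), a rho of 0.13 (adjusted permutation p = 0.139), 0.26 without the 2 farthest and -0.033 within numeric libraries. Within E21 libraries their r of 0.40 passed (adjusted permutation p = 0.000994), while the rho of 0.17 did not (adjusted permutation p = 0.161), and with the first principal component removed the r of 0.20 passed (adjusted permutation p = 0.0145). The clock arms had an r of 0.029 (permutation p = 0.724), a rho of -0.050 (permutation p = 0.546), -0.066 without the 2 farthest, -0.11 within numeric and 0.15 within E21 libraries. With the first principal component removed their rho of -0.17 passed (adjusted permutation p = 0.0356), while the r of -0.13 did not (adjusted permutation p = 0.13). None of the 15 pairs differed between formats in a permutation test of the difference after adjustment. The smallest permutation p was 0.0178, for the cortical and GABA pair, with an adjusted p of 0.21.

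**Figure D4:**
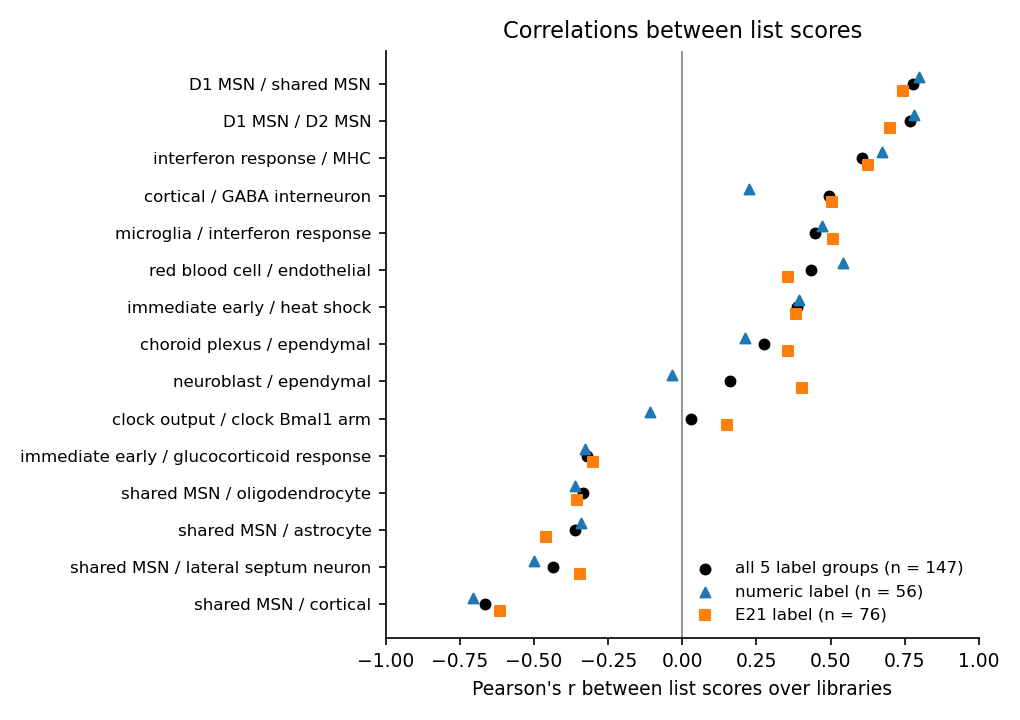
Pearson's r between list scores (x axis) for the 15 preset pairs over 147 libraries and within the numeric (n = 56) and E21 (n = 76) libraries left after 12 of other profile. The r of shared medium spiny neuron (MSN) and cortical scores lay between -0.71 and -0.61 in these sets, and that of the clock arms between -0.11 and 0.15.

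Genes next to each other on a chromosome varied together more than genes on different chromosomes. The median r was 0.15 for 2559 pairs under 10 kb apart, 0.088 for 7540 pairs at 10 to 100 kb and 0.083 for 4791 pairs at 100 kb to 1 Mb, against 0.024 on different chromosomes (p = 0.001 for each, the smallest that shuffles of positions can give). After removal of 10 principal components the medians were 0.041, 0.029 and 0.026, against 0.0022. The complement genes C1qc and C1qa had an r of 0.91 and the alpha globin genes Hba-a2 and Hba-a1 0.98. The beta globin neighbours Hbbl1 and Hbb-b2 had -0.84, and Cers1 and Gdf1, which start at one position, 1.0. These pairs were chosen after their values were seen, and values of globin copies and of overlapping genes are uncertain, since they can share reads.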

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

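The alternatives that left out libraries of midbrain or cortical profile or E21 label number 20, those with the cortical score or the first component of the remaining 147 libraries, voom, and neighbouring genes over all libraries were chosen after the data were seen, and the others before. Of the alternative values of counts and main results 69 were taken as stable and 56 were not. Stable meant within 1.5 times for counts and within 1 bootstrap SD for the median SD. For neighbouring genes it meant only the same direction and side of the threshold. Their median r under 10 kb was taken as stable though it fell from 0.15 to 0.041 with 10 principal components removed. Of the alternative values of single genes, lists and pairs, 1512 kept their direction and side of the threshold or, for SDs of single genes, stayed within 1 SE. A further 234 no longer passed, 38 newly passed, 50 without a test moved and 59 turned direction. The cause was not tested, except where fewer libraries or genes went in. Planned level differences between genes of a rat, the comparison of removed with retained libraries and the pairing of mitochondrial with ribosomal genes were not run. Genes near 1 CPM rest on as few as 14.6 expected counts in the shallowest library.

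The count of 7355 genes called between formats became 3749 without libraries of low median correlation and 4849 without those of midbrain or cortical profile and with the first component of the 147. The 488 with an absolute log2 change of at least 0.5 became 283 at a mean of at least 10 CPM, 833 at a pseudocount of 0.1, 202 at a pseudocount of 5, 169 with the first principal component as a covariate, 119 without libraries of low median correlation, 181 without the midbrain profile, 178 without midbrain or cortical profile, then 130 with the cortical score and 117 with the first component of the 147, and 852 with voom. After label correction the 791 genes became 1603 with the first principal component, 1 with 3 list scores (Fbln7), 1701 without libraries of low median correlation, 1386 by the Wilcoxon test, 1265 without the midbrain profile (the 1 such library, E21 label number 70) and again 1265 without midbrain or cortical profile, then 12 with the cortical score (4534 at an unadjusted p under 0.05) and 2069 with the first component of the 147. With numeric libraries as the reference limma called 0 (1268 at an unadjusted p under 0.05), and 0 without those profiles (1216). The 214 at an absolute log2 change of at least 0.5 became 111 at a mean of at least 10 CPM, 115 at a pseudocount of 5, 0 with 3 list scores, 0 with the numeric reference, 2 with the cortical score (LOC120103069 and Cep131, named after their values were seen), 328 with voom and 0 with the numeric reference without those profiles. Camera in limma called 8 lists between formats, 0 with an estimated correlation, 3 without those profiles and 0 with both. After correction it called 3, then 0, 6 and 0.

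The median SD of 0.27 was 0.25 in numeric libraries, 0.21 without libraries of low median correlation, 0.30 at a pseudocount of 0.1, 0.24 at a mean of at least 10 CPM, 0.24 without midbrain or cortical profile, and 0.19 and 0.26 in numeric and E21 libraries without them. The 1791 genes of SD at least 0.5 were 1171 in E21 libraries, 536 without libraries of low median correlation, 3140 at a pseudocount of 0.1, 883 at a mean of at least 10 CPM, 781 without those profiles, and 445 and 991 in numeric and E21 libraries without them. The 357 genes of 2 separated levels were 800 at a gap of 0.5, 14 at 10% of libraries a side, 27 in E21 libraries, 16 without those profiles, then 40 at a gap of 0.5 and 16 at 10%. Of 15 score pairs 13 passed, and 3 did among the 11 libraries of midbrain profile.

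Some log2 changes between formats turned direction. With the first principal component Ankrd63 was -0.013, Th 0.24, Slc6a3 0.22, Chrm4 -0.033 and Npas2 -0.022. Without the midbrain profile Th was 0.0013, and without both profiles 0.019. With the cortical score as well, Ankrd63 was -0.018, Th 0.063, Slc6a3 0.020, Cck 0.17, Pdyn -0.041, Chrm4 -0.011, Gng7 -0.0035, Neurod6 0.067 and Tef -0.047. Without libraries of low median correlation Slc6a3 was 0.0034 and Dbp -0.0009, and Dbp was -0.015 with the first component of the 147. With 3 list scores Neurod2 was 0.0058. After label correction, the cortical score without those profiles gave Slc17a7 -0.26, Ccn3 -0.0026, Tbr1 -0.14 and Neurod6 -0.032, and 3 list scores gave Slc17a7 -0.23, Ccn3 -0.079, Tbr1 -0.18, Cplx3 -0.019, Gng7 0.021 and Neurod6 -0.047. Slc17a7, Tbr1, Neurod2 and Neurod6 are themselves members of the cortical list that makes up this score. Changes near 0, of either sign, were thus largely fixed for them, and their turns in both comparisons decide nothing. Pde10a was -0.028 without libraries of low median correlation and -0.092 with the first component of the 147. Against numeric libraries Rps14-ps7 was -0.22, Rn45s 0.0089, Rpl37 0.079, Drd2 0.15, Gpr6 0.70, Gpr52 0.45, Adora2a 0.90, Gng7 0.69, Arpp21 0.87, Lhx8 0.29, Slc18a3 0.16 and Rpl8l1 0.013, and without those profiles Rps14-ps7 was -0.30, Rn45s 0.18, Rpl37 0.043 and Rpl8l1 0.052. Values and counts with the numeric reference belong to another comparison, whose reference holds 10 libraries of midbrain profile unless these are left out. They do not show how stable the changes against E21 libraries are. Among score pairs, r within the midbrain profile was 0.43 for shared medium spiny and cortical, 0.11 for shared and astrocyte, -0.29 for choroid plexus and ependymal, 0.18 for immediate early and glucocorticoid, -0.090 for the clock arms and -0.033 for neuroblast and ependymal scores. The clock arms also had -0.090 without libraries of low median correlation, -0.11 in numeric libraries, -0.035 with quantile normalization and -0.13 with the first principal component removed, and neuroblast and ependymal scores -0.033 in numeric libraries.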

Other observations

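All tests in this part, the splits of libraries included, had what they would show set down only after the results were seen.

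In 352 pairs of a gene copy and its parent gene, 14 copies had an SD of at least 1 over 147 libraries. Of these 14, 11 had a negative r with the parent across libraries, with a median r of -0.31 over the 14, against 0.23 for the other 338 pairs. Rpl30l2 and Rpl30 had an r of -0.68, and the SD was 2.39 for the copy and 0.33 for the sum of both. Rps14-ps7 and Rps14 had -0.58, and the SD was 2.17 for the copy and 0.34 for the sum. Numbers 4 and 63 of the numeric label, both of midbrain profile, had Tph2 at 57.4 and 57.5 CPM and Slc6a4 at 26.4 and 37.6, genes of serotonin neurons.

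In 11 libraries the genes of midbrain dopamine neurons stood in place of those of the striatum, with Th at 630 to 2107 CPM. The median level of 12 D1 and D2 list genes lay between 4.04% and 8.57% of that in the remaining libraries. Accumbens tissue with some midbrain tissue mixed in would keep most of it. However, Drd1 and Adora2a of these lists were among the genes with the strongest loadings on the component that set these libraries apart. Low levels were thus in part fixed by that choice, and the test does not decide against a mixture. Drd2, also on the lists, kept a median of 122 CPM, against 186 in the 147 remaining libraries. All 6 tested midbrain dopamine genes lay above the highest of the remaining libraries in 11 of these 11, but 5 of the 6 were among the genes with the strongest loadings on the component that set these libraries apart, so that this test decides nothing about whole libraries of another brain region under an accumbens label. The longest run of neighbouring numeric identifiers with this profile was 6 of the 10, with a permutation p of 0.00011, so these libraries could have been handled next to each other. Whether samples were exchanged, another region was dissected or neither stays open, and no biological explanation was tested.

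Cortical gene levels differed between label groups, with a median cortical share of 4.44% in E21, 11.3% in numeric and 19.4% in corrected E21 libraries among the 147. The share is the median over the 8 cortical genes of the level above the lowest of the 147, as a percent of that in number 3 of the numeric label. It is a scale set by that 1 library, whose purity was not tested, and no percentage of tissue. Library depth is argued against, as the cortical score had an r with total counts of 0.2207 within numeric and -0.1311 within E21 libraries. With the first principal component of these 147 libraries the ribosomal protein score had an r of -0.746. The cortical score had -0.106 with that component and 0.947 with the second one. A covariate so little related to the cortical genes could hardly shrink their change. With it 122.11% of the median cortical change between formats was left (-0.90 before, -1.10 after), which therefore does not decide on that trend as a source. RNA quality was not measured and stays open. Of 7 tested genes annotated as ribosomal RNA, whose copies can share reads, limma called 4 higher in E21 than in numeric libraries over all libraries, 6 among the 147 and 4 there with the cortical score as a covariate. Rn18s and LOC120102105, both among the 6, hold identical values and are not separate evidence. Rn5-8s, at -0.041 among the 147, was not called. As a group the 7 genes were not tested. Neighbouring cortical tissue in the dissected piece may be a candidate source, since medium spiny neuron genes were lower at higher shares in 23 of 24 cases, with a fitted median of -4.52% of their level at a full share (95% bootstrap interval -16.9% to 9.99%), where the cortical library had 9.39%. That fit reaches beyond the highest share seen, 50.8%, and to levels below 0, and all 8 cortical genes, of which Slc17a7 had a median of 197 CPM in these libraries, are on no other list but were at 1 CPM or more on average here. No biological explanation was tested, since batch and rat origin cannot be told apart. Identifier format can be told apart in part, since the 12 corrected libraries carry E21 identifiers. Over all genes, limma called 791 between them and the E21 libraries and 0 against the numeric ones. That argues against identifier format alone as the source of the differences. The limit is that 12 libraries are few and 3 of 100 splits called at least 791 genes.

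In E21 label number 20, Xist was at 40.0% of its median in 82 other libraries and the 4 Y-linked genes at a median of 57.76% of theirs in 76 others. A single rat with 2 X chromosomes and a Y is argued against by that 57.76%, with 2 of the 4 genes at or below the lowest of the others. The shares of Xist and of the Y-linked genes add up to 97.76%, so that material of 2 rats in 1 library may be the source. However, Xist ranged from 106 to 1272 CPM in the 82 others, and the 309 CPM here lay within that range. The sum is therefore weak evidence. This library had 53.4 M expected counts, where the next deepest of its group had 30.6 M.

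In the comparison of formats 1 of 100 splits of single libraries, the real one, called as many as 7355 genes, and the highest other called 2162. Without the 12 libraries of midbrain or cortical profile the real split called 5796 and the highest other 807. A chance split of single libraries is thus argued against, at the smallest share that 100 splits can give. Splits of whole batches were not made, so a chance difference between batches is not excluded. After label correction 3 of 100 splits called at least the real 791 genes, with 1817 in the highest other. That share is under 0.05 but, at 100 splits, too near it for chance to be excluded firmly. What the split with 1817 calls set apart was not tested.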
